A study of Mus musculus with 3 samples.

How the data were processed

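The series holds 3 libraries from Ebf1-deficient mouse pro-B cells with induced NICD1: an EBF1wt ChIP, an EBF1E271A ChIP and an input, 1 per group. Per the labels' protocols, each ChIP used 20 µg of chromatin and 4 µg of an EBF1 antibody after 10 minutes of crosslinking, on mouse cells mixed with human BJAB cells at 10 to 1. The antibody binds mouse and human EBF1.

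The deposited values are a signal: per the file headers they are scaled counts per region for the EBF1wt and EBF1E271A libraries, and per the labels the authors used human spike-in chromatin for normalization. The submitters' processing notes name Bowtie2 2.3.5.1, SAMtools 1.10, MACS2 2.2.7.1, bedtools 2.27.0 and deepTools 3.5.0 and 3.3.2, with the mouse build GRCm38 and human builds. How each was used, how the regions were called and how the scale factors were computed is not given in the sources used here. The values themselves show part of the scaling. Every value is a whole multiple of 1 step per library, 1.5811 for EBF1wt and 0.6325 for EBF1E271A, within a tolerance of 0.001 counts for 100% of the values. The steps multiply to 1 and have a ratio of 2.5, so dividing by the step gave the unscaled counts. This recovery rests on the values and not on a stated factor.

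The 4116 regions are identical in the table of values and in the list of positions. All are 300 bp wide and none has a value at or below 100 in both libraries. They include 31 exact duplicates, and overlapping regions form 2121 loci, 1995 of 2 regions and 126 of 1. Regions were analysed as deposited, with loci as an alternative, and named loci are given by the overlapping region with the higher mean value. The build was taken as GRCm38 from the notes and from the chromosome names. Start positions were taken as counted from 0, from the width, and are printed counted from 1.

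The ratio of EBF1E271A over EBF1wt was taken per region, and log2 ratios were computed after a pseudocount of 1 on the scaled values. Medians carry 95% binomial intervals of the median, which treat regions as independent although overlapping regions are not. Ratios of single regions carry exact binomial (Clopper-Pearson) 95% intervals of the unscaled counts, multiplied by the ratio of the steps. PCR copies are not separate molecules, so these intervals cover counting error only. Intervals assume that the scale factors have no error, since the human read counts were not used here. With 1 library per group, no p-value between the conditions was computed, and changes were counted by a rule of size (2-fold on the log2 scale after the pseudocount).

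Genes came from a RefSeq gene table of GRCm38.p6 with 21900 protein-coding genes and no strand. The planned assignment by transcription start site was therefore replaced by the nearest protein-coding gene body within 100 kb of the region's centre, and the planned promoter class by regions within 1 kb of either gene end. Exons, introns and UTRs were not analysed here. Gene lists (8 lists, 207 genes, all found in the table) were written before the data were examined. A list's median was set against 10000 random sets of as many regions, drawn within 20 strata of mean value, and its percentile describes these libraries only. Overlapping regions of 1 locus are not independent, so percentiles with each locus counted once are the more cautious ones.

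The design, the lists, the settings given first below and the rule for named genes were fixed before the data were examined. The rule names the 8 regions with the lowest and the 8 with the highest log2 ratio among regions whose mean value is at or above the median, and the 8 with the highest EBF1wt value. It also names the strongest region of each of the 3 genes per list with the highest mean value, and the strongest region near each gene of a preset group (Ebf1, Pax5, Cd79a, Cd79b, Igll1, Vpreb1, Foxo1, Notch1, Hes1, Gata3, Tcf7, Rbpj and 1 gene that is not reported here). Counting an overlapping pair once in this rule, and naming the list members with the lowest and highest ratios and the loci of the chromosome 5 interval, were chosen after the values were seen.

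Settings chosen before the data were seen were equal sums of both libraries, a pseudocount of 10, regions at or above the lower quartile or the median in mean value, the ratio of sums, a 1.5-fold rule, ratios relative to the median, quintiles by the EBF1wt value, genes within 10 kb and all genes within 50 kb. Added after seeing the data were loci counted once, equal sums without the highest region, the 2.5 kb window at gene ends and leaving out 130 to 140 Mb of chromosome 5. Genomic intervals of 10 Mb with at least 5 loci were compared with 10000 shuffles of the ratios over all loci, also after seeing the data. Subtraction of input, ratios by sequence motif and promoters by start site were planned and not run, since no input value per region, genome sequence or strand was used here.

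The ratio, rule and intervals were tested on simulated data for the comparison of EBF1E271A with EBF1wt, with the 4116 regions at their real means. The simulated folds were relative to the median ratio of 0.901, whereas the 2-fold rule was applied to the scaled ratio itself. It took 100% of regions simulated at 0.25-fold, 74% at 0.5-fold, 0% at 1-fold, 20% at 2-fold and 100% at 4-fold. Of the intervals, 92% to 98% held the true ratio. The simulated noise was counting error alone, which the intervals assume, so this coverage does not extend to the wider spread of the real ratios. The depth, a median of 91 unscaled counts per region for EBF1wt and 209 for EBF1E271A, gave a median counting error of 0.18 per log2 ratio. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.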

Results

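Occupancy of EBF1, the transcription factor that specifies the B lineage, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse pro-B cells. The cells grew from c-kit-positive progenitors of Ebf1-deficient fetal liver and carried a doxycycline-controlled NICD1, the intracellular domain of the Notch1 receptor. They received EBF1 back from a retrovirus, either as the wild-type protein (EBF1wt) or with an amino acid substitution (EBF1E271A). Doxycycline was present at 1 µg/ml for 6 hours before fixation. Cells of the human B lymphoma line BJAB, which makes its own EBF1, were mixed in at 10 mouse cells per human cell so that human chromatin could set the scale between libraries. The series holds 3 libraries, 1 per group: an EBF1wt ChIP, an EBF1E271A ChIP and an input. The design asks how far the substituted protein occupies the sites of the wild-type protein while NICD1 is induced.

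Spike-in scaled counts were given for both ChIP libraries at 4116 regions of 300 bp, which overlap into 2121 loci. No input value per region was used here. Before scaling, the regions held 515897 counts in the EBF1wt library and 1105818 in the EBF1E271A library, with a median per region of 91 and 209. A read in overlapping regions is counted in each, and the totals of the whole libraries were not used here. With 1 library per group no difference has a replicate check, and no test between the conditions was possible. The 95% intervals of single regions are exact binomial (Clopper-Pearson) intervals from the unscaled counts and cover counting error only. Ratios are EBF1E271A over EBF1wt throughout, and all coordinates are GRCm38.

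At the 25 loci nearest to B lineage genes, most scaled counts of EBF1E271A were close to those of EBF1wt. The ratio was below 1 at 15 of these loci and at or above 1 at 10, with 2 at least 1.5-fold lower and 0 at least 1.5-fold higher. This direction depends on the spike-in scale, and without an input value per region the counts alone do not show binding. Beside Igll1, which encodes the λ5 part of the surrogate light chain, the values were 433.2 for EBF1wt and 361.2 for EBF1E271A. Inside Pax5, which encodes a transcription factor of B cell commitment, they were 330.4 and 304.9. Of the 4116 regions, 2852 exceeded a scaled count of 100 in both libraries, 925 in EBF1wt alone and 339 in EBF1E271A alone. Each region exceeded 100 in at least 1 library.

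The median ratio over all regions was 0.901 (95% binomial interval 0.894 to 0.910), a log2 ratio of -0.15, with quartiles of -0.38 and 0.08. The ratio lay below 1 at 66.8% of the regions. This direction rests on the spike-in scale: with both libraries scaled to equal sums over the regions, the median log2 ratio was 0.07. With the region of highest value left out of the sums, it was 0.0029. Equal sums remove any change shared by all regions, so they do not test the spike-in scale. Scaling to equal sums shifts every log2 ratio by 0.22, or by 0.15 without that region in the sums. Gene lists are therefore given below relative to the median of all regions. Across regions, which are not independent replicates, the values of the libraries had a Spearman correlation of 0.772. The log2 ratios had an SD of 0.456, against 0.181 from counting error alone, and the interval of 33.1% of the regions excluded the median ratio, against 5% from counting error.

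By a fixed rule of size, 167 regions (93 loci) were at least 2-fold lower in the EBF1E271A library. By the same rule 26 regions (19 loci) were at least 2-fold higher, while 3923 regions lay within 2-fold. The weakest quintile by mean value of both libraries held 93 of the lower and 17 of the higher regions, the strongest 20 and 2. In that weakest quintile, 583 of 824 regions exceeded 100 in EBF1wt alone and 235 in EBF1E271A alone, so the making of the list shapes these counts. Taken relative to the median ratio, 116 regions were lower and 44 higher, and with equal sums 96 were lower and 55 higher. Among regions at or above the median in mean value, the lowest ratio lay inside Cdk17, a cyclin-dependent kinase gene (chromosome 10, 93198374 to 93198673), with scaled counts of 877.5 for EBF1wt and 94.2 for EBF1E271A, a ratio of 0.107 (0.0890 to 0.129). Regions inside Castor2 (chromosome 5, 134121774 to 134122073) and inside the exocyst gene Exoc6 (chromosome 19, 37677704 to 37678003) followed at 0.299 (0.232 to 0.384) and 0.301 (0.248 to 0.365). A pair of regions inside Auts2, a gene of neural development, had ratios of 0.342 and 0.351 (chromosome 5, 131853310 to 131853609 and 131648473 to 131648772). The other low regions lay outside genes, 77.8 kb from Lgalsl (ratio 0.340), 24.3 kb from the ribonuclease P subunit gene Rpp21 (0.384) and 13.4 kb from Icosl, which encodes the ligand of the costimulatory receptor ICOS (0.387).

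The highest ratio among these regions lay inside Rad51b, a gene of homologous recombination (chromosome 12, 79793394 to 79793693), with scaled counts of 181.8 for EBF1wt and 384.6 for EBF1E271A, a ratio of 2.11 (1.73 to 2.60). A region 9.88 kb from the RNA-binding protein gene Mex3a had a ratio of 2.01 (1.53 to 2.66), and one 10.8 kb from Nkd1, which encodes a Wnt pathway antagonist, 1.83 (1.44 to 2.36). Further high ratios were found inside Dipk1b (1.72) and at regions outside Neurl1b (1.72), Erv3 (1.68), Yaf2 (1.61) and the cytoplasmic actin gene Actg1 (1.59).

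**Figure D1:**
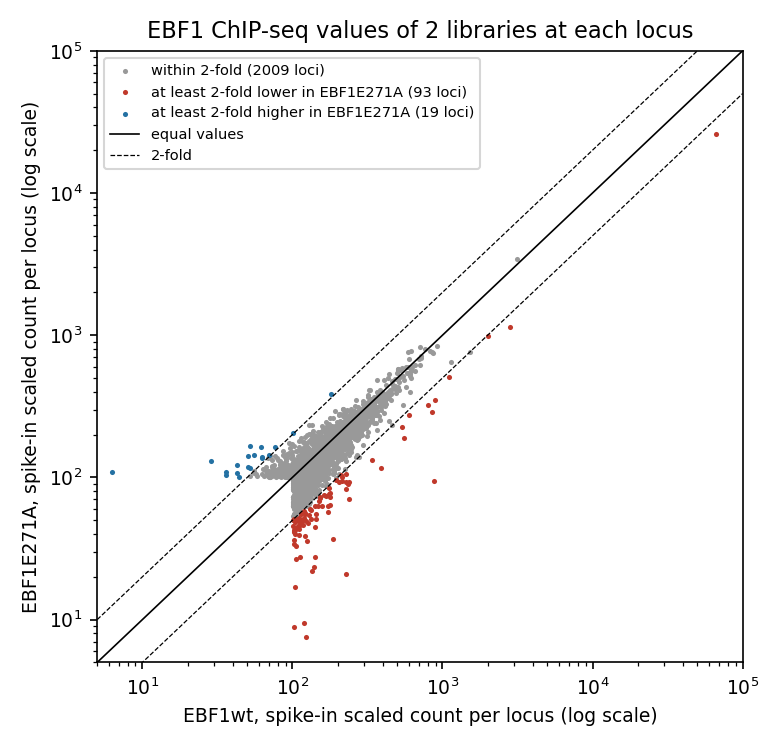
Spike-in scaled count per locus in the EBF1wt library (x axis, log scale) and in the EBF1E271A library (y axis, log scale), 1 library each. Each point is 1 of 2121 loci, the solid line marks equal values and the dashed lines 2-fold differences. The 93 loci at least 2-fold lower in EBF1E271A lie below the lower dashed line and the 19 at least 2-fold higher above the upper one, and the region of chromosome 2 with 66811 for EBF1wt lies farthest to the right.

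The region with the highest EBF1wt value lay on chromosome 2 (98666651 to 98666950), with no protein-coding gene within 100 kb. Its scaled counts were 66811 for EBF1wt and 26048 for EBF1E271A, a ratio of 0.390 (0.385 to 0.395), and it held 8.19% and 3.72% of the sums of the libraries. The ratio of the sums over all regions was 0.857 with this region and 0.899 without it. The 8 loci with the highest EBF1wt values were chosen by the denominator of the ratio, which by itself favours low ratios. Of these 8 loci, 6 had a ratio below 0.6, against 8.44% of all loci and 4.57% of those at or above the median in mean value. These were the chromosome 2 locus, a locus 64.4 kb from Sh3gl3 (0.402), a locus on chromosome 3 with no protein-coding gene within 100 kb (5860472 to 5860771, ratio 0.458), 2 loci on chromosome 17 within 2.5 kb of the ribosomal RNA pseudogene Rn18s-rs5 (0.488 and 0.501) and a locus inside Slc25a26, a mitochondrial carrier gene (0.567). The remaining pair were a locus inside the long noncoding RNA gene Gm35814 on chromosome 18 (10918376 to 10918675), with 3124 for EBF1wt, 3450 for EBF1E271A and a ratio of 1.104 (1.05 to 1.16), and a locus on chromosome 8 (12048295 to 12048594) with a ratio of 0.912.

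B lineage genes had ratios close to those of all regions. Loci were found nearest to 20 of the 42 listed genes. The median log2 ratio of their 50 regions lay 0.07 above that of all regions, at the 83.6th percentile of 10000 random sets matched on mean value. With each of the 25 loci counted once, the list lay at the 74.0th percentile. Of the 25 loci, 4 had an interval above the median ratio, 2 an interval below it, and 19 an interval that held it. Those above it included loci inside Ciita, the transactivator of MHC class II genes (368.4 for EBF1wt, 482.0 for EBF1E271A, ratio 1.31, 1.13 to 1.52), and inside the ETS factor gene Erg (414.2 and 483.2, ratio 1.17, 1.01 to 1.35), with the other two near Vpreb2 and inside Bank1. Those below it were near Cd72, an inhibitory B cell coreceptor gene (107.5 and 51.2, ratio 0.477, 0.341 to 0.668), and near Ralgps2 (0.649). Regions at Ebf1 itself had ratios of 0.972 and 1.13, those at Pax5 0.923 and 0.907, and that near Foxo1 0.805, all with intervals that held the median ratio.

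Genes of the pre-B cell receptor and its signalling had a median log2 ratio 0.05 below that of all regions. It was -0.19 over 46 regions near 17 of the 30 listed genes, at the 13.7th percentile of matched sets, and at the 19.1st with each of the 23 loci counted once. This list shares 8 loci with the B lineage list. The receptor genes Igll1, Cd79a and Cd79b had ratios of 0.834 (0.721 to 0.966), 0.831 (0.694 to 0.999) and 0.937 (0.754 to 1.17). A region 9.77 kb from Vpreb2, which encodes another surrogate light chain part, had a ratio of 1.17, and one inside the gene 0.721. No locus had Vpreb1 as its nearest gene. Inside Nfatc1, a calcium-regulated transcription factor gene, the ratio was 0.566 (0.441 to 0.728), whereas 2 loci outside that gene had 0.896 and 1.17. Beside Ptpn6, which encodes the phosphatase SHP-1, it was 1.33 (0.987 to 1.83).

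Notch pathway genes, like B lineage genes, had ratios close to those of all regions. Loci were found near 8 of 25 Notch genes, and their 19 regions had a median log2 ratio 0.10 above that of all regions, at the 83.2nd percentile, and at the 70.1st with each of the 10 loci counted once. Ratios were 0.967 inside Maml1, 0.898 inside Notch3, 0.918 inside Dtx1, 0.911 near Hes1 and 0.990 near Notch1, each with an interval that held the median ratio. Of the 10 loci, only that inside the coactivator gene Maml3 (0.608, 0.449 to 0.829) and that 97.6 kb from the cyclin gene Ccnd1 (1.41, 1.11 to 1.81) had intervals that excluded it. No locus lay nearest to Rbpj, which encodes the DNA-binding partner of NICD1. Among regions at or above the median in mean value, the Notch list lay 0.0025 above the median of those regions.

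The 5 of 26 T lineage genes with a locus had a median log2 ratio 0.26 above that of all regions over 12 regions, at the 98.1st percentile, and at the 94.1st percentile with each of the 6 loci counted once. The interval of the median over the 6 loci, -0.19 to 1.15, held the median of all loci, -0.15, and 4 of the 6 loci had an interval that held the median ratio. It lay 0.12 above the median of the regions at or above the median in mean value, and 0.14 above that of all regions with all genes within 50 kb considered. The highest ratio, 2.29 (1.62 to 3.303), lay 3.98 kb from Runx3, with scaled counts of 61.7 for EBF1wt and 141.0 for EBF1E271A. This locus and a locus of Il2ra (85.4 and 100.6) exceeded 100 in EBF1E271A alone, as did 339 of all 4116 regions. Such loci have ratios above 1 by construction, so part of the list's position may come from how the list of regions was made. Beside Tcf7, which encodes the T cell factor TCF1, the values were 251.4 and 289.7 (ratio 1.15, 0.960 to 1.39). Ratios were 1.00 inside Tox, 0.887 near Runx1, and 1.18 and 0.992 at 2 loci of Il2ra, a gene that is also on the Notch list. No locus lay nearest to Gata3.

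Myeloid and innate lymphoid genes had a median log2 ratio 0.05 below that of all regions, over 11 regions near 5 of 26 genes. This was the 27.0th percentile, and the 35.9th with each of the 6 loci counted once. Inside Itgam, the gene of the integrin subunit CD11b, the values were 706.8 and 614.8 (ratio 0.870, 0.777 to 0.975), and near Id2 and inside Flt3 the ratios were 0.865 and 0.885. The lowest ratios of the list were 17.5 kb from Csf2ra (0.404, 0.303 to 0.539) and 64.9 kb from Cebpb (0.521, 0.401 to 0.677). Stroma and adipocyte genes, listed because the cells had been grown on OP9 feeder cells, had 8 regions near 3 of 22 genes and lay 0.19 above the median of all regions, at the 95.6th percentile, and at the 90.1st with each of the 4 loci counted once. Their ratios were 1.00 near Adipoq, 1.06 and 0.800 inside Zfp423 and 1.22 near Runx2. Cell cycle and survival genes, with 19 regions near 7 of 23 genes, lay 0.04 above the median of all regions, at the 59.9th percentile. With each of the 10 loci counted once they lay at the 54.75th percentile, and with genes within 10 kb only 0.07 below the median of all regions. Inside Bcl2l1, which encodes the survival protein Bcl-xL, the values were 381.0 and 256.8 (ratio 0.674, 0.573 to 0.794), inside Bcl2 the ratio was 0.911 and near Bcl6 0.956. Of the ribosome, translation and housekeeping list only Actb, 1 of 25 genes, had a locus, 16.3 kb away, with a ratio of 0.744 (0.608 to 0.914).

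**Figure D2:**
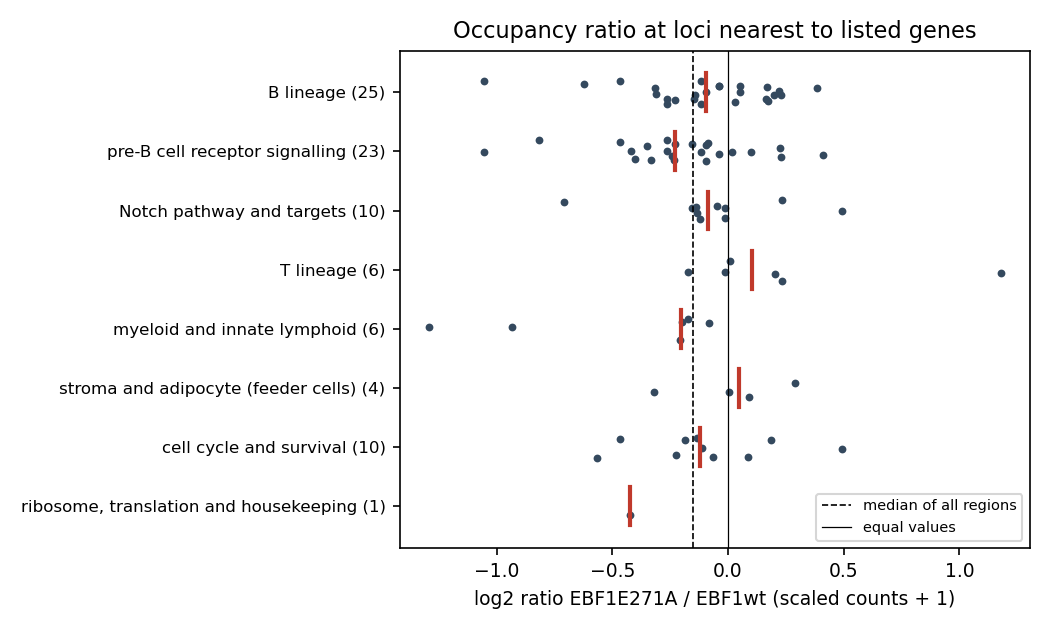
Log2 ratio of EBF1E271A over EBF1wt (x axis, scaled counts plus 1) at the loci nearest to genes of the 8 lists, with the number of loci in brackets. Each point is the region with the higher mean value of 1 locus, the red bars are the medians of the points, the dashed line is the median of all regions (-0.15) and the solid line marks equal values. The Runx3 locus lies farthest to the right, at 1.18, and the Csf2ra locus farthest to the left, at -1.29.

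Low ratios were concentrated on chromosome 5 between 130 and 140 Mb. This interval held 50 loci, the most of the 155 intervals of 10 Mb with at least 5 loci, and their median log2 ratio was -0.60 (-0.98 to -0.45), against -0.14 at the 2071 loci elsewhere. Of the 50 loci, 42 lay below the median elsewhere and 16 (32%) were at least 2-fold lower, against 3.72% elsewhere. In the interval 26 loci (52%) exceeded 100 in EBF1wt alone, against 22.7% elsewhere, and 1 in EBF1E271A alone. Loci that exceeded 100 in EBF1wt alone have ratios below 1 by construction, so part of this contrast may come from how the list was made. The low loci included 1 that lay 36.5 kb from the elastin gene Eln (ratio 0.198, 0.143 to 0.273), 1 inside Eln (0.335), both loci of Auts2 named above, that in Castor2, and loci inside the huntingtin-interacting protein gene Hip1 (0.379 and 0.444), inside the cytochrome P450 reductase gene Por (0.435) and 22.3 kb from Cux1 (0.416). The other loci inside Hip1 had ratios of 0.821 (0.711 to 0.951) and 1.18 (0.881 to 1.60), the latter the highest of the interval. The median scaled count in the interval was 163 for EBF1wt and 97.1 for EBF1E271A, against 142 and 131 elsewhere. Without this interval the median log2 ratio of all regions was -0.14, with 136 regions at least 2-fold lower and 26 higher.

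**Figure D3:**
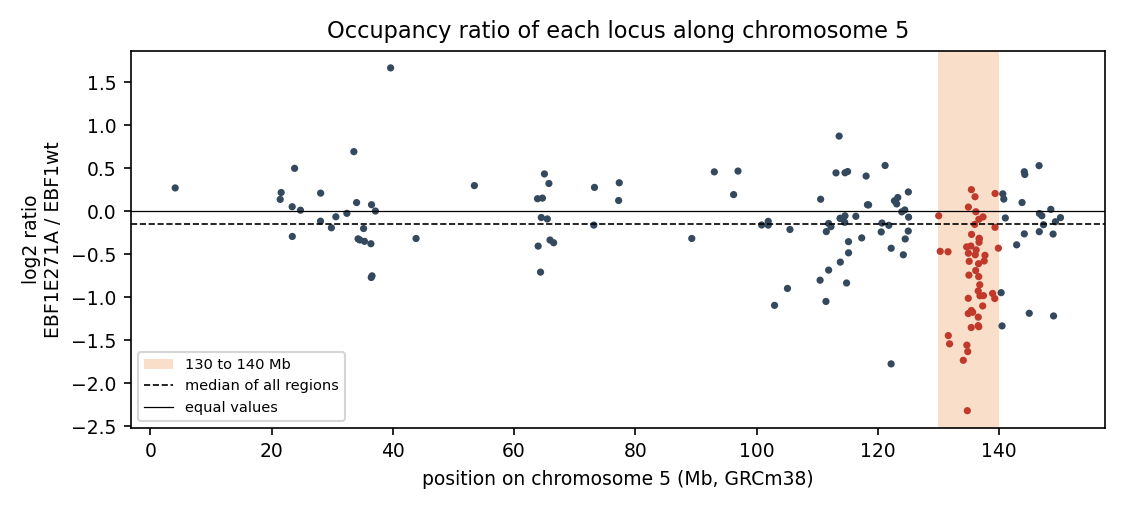
Log2 ratio of EBF1E271A over EBF1wt (y axis) at each locus along chromosome 5 (x axis, Mb, GRCm38), 1 library each. The 50 loci between 130 and 140 Mb are red on a shaded band and have a median of -0.60, below the median of all regions (-0.15, dashed), with the lowest locus at -2.32. The solid line marks equal values.

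Regions at gene ends, inside genes and between genes had nearly equal ratios. The 615 regions within 1 kb of either end of a protein-coding gene had a median log2 ratio of -0.15, the 1905 further inside genes -0.15 and the 1595 between genes -0.14, at the 45.8th, 51.7th and 50.3rd percentiles of matched sets. By mean value of both libraries, the weakest quintile of the regions had a median log2 ratio of -0.34 and the strongest -0.11. The quintiles between them had -0.15, -0.13 and -0.11. The weakest quintile is shaped by how the list was made: 583 of its 824 regions exceeded 100 in EBF1wt alone and 235 in EBF1E271A alone. Ordered by the EBF1wt value, the difference turned around, with 0.09 in the weakest quintile and -0.15 in the strongest. The ordering itself favours this turn: all 339 regions that exceeded 100 in EBF1E271A alone fell in the weakest quintile by EBF1wt value.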

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

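Counting each locus once, leaving out 130 to 140 Mb of chromosome 5 and equal sums without the highest region were chosen after the results were seen, and the other settings named here were planned. Of the settings run, 78 values stayed within their interval or, for counts, within 1.5 times, 18 moved and 5 reversed. Many of the 78 could hardly move, so this tally does not measure robustness. Lists and the gene-end difference are relative to other regions, so equal sums leave them nearly unchanged by construction. No listed locus lay between 130 and 140 Mb of chromosome 5, so leaving it out moved each list only with the median of all regions. With equal sums the median log2 ratio turned from -0.15 to 0.071 (0.0029 when the highest region was left out of the sums), with 96 regions at least 2-fold lower and 55 higher. The ratio of sums gave -0.22. Without regions below the lower quartile of mean value the median was -0.12, with 71 lower and 8 higher, and at or above the median of mean value it was -0.11, with 42 and 3, where fewer regions were counted. A 1.5-fold rule gave 552 and 122, ratios relative to the median gave 44 higher, and each locus counted once gave 93 lower, fewer by construction. The weakest quintile minus the strongest, -0.23, was -0.20 with a pseudocount of 10, -0.033 without the regions below the lower quartile and 0.014 at or above the median. By EBF1wt value it was 0.24, a turn that ordering by the denominator of the ratio itself favours. The T lineage list, 0.26 above the median of all regions, was 0.12 above the median of each of these stricter sets and 0.14 above that of all regions with all genes within 50 kb. The Notch list, 0.10 above, was 0.0025 above among regions at or above the median. The ribosome and housekeeping list, -0.24 from Actb alone, was 0.062 with all genes within 50 kb and gave no value with genes within 10 kb. Beyond what each setting does by construction, the cause was not tested. Input subtraction, motifs and promoters by start site were not run. Depth limits single regions to a median counting error of 0.18 on the log2 scale.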

Other observations

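The tests below were chosen after the results they bear on were seen. Among the 17 genes nearest to at least 4 loci, the 4 loci inside Tenm4, a teneurin gene on chromosome 7, were all lower in the EBF1E271A library, with log2 ratios between -1.07 and -0.64. Nav2, on the same chromosome, had 5 loci with a median of -0.55 and a range from -0.96 to 0.18. Cux1, Hip1, Myl10 and Col26a1, with medians of -1.08, -0.71, -0.61 and -0.59, all lie in the chromosome 5 interval. In the same order, their loci ranged from -1.33 to -0.45, from -1.35 to 0.25, from -1.34 to -0.10 and from -0.99 to -0.32. At the other end, the 4 loci of Rad51b had a median of 0.22 and those of Iqsec1 and Tns3 0.06 each. Smad3, a signal transducer of TGF-β, had 4 loci from -0.93 to -0.02.

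By chromosome, the lowest percentiles of matched sets were the 1.94th of chromosome 7 (163 loci, median log2 ratio -0.20) and the 6.01st of chromosome 19 (63 loci, -0.21). The X chromosome followed at the 8.68th (13 loci, -0.37), and the highest was the 98.8th of chromosome 14 (82 loci, -0.04). These are the extremes of all chromosomes compared, and among so many sets some may lie this far out by chance. Chromosome 5, which holds the low interval, lay at the 13.6th (161 loci, -0.19). Loci made of a single region differed more often than those made of an overlapping pair: 26.2% of 126 were past 2-fold (21 lower and 12 higher), against 3.96% of 1995 (72 and 7). How the regions were called is not given in the sources used here, and if a single region marks a locus called in 1 library only, this contrast follows from how the list was made. The highest ratio of all loci, 17.3 (6.64 to 64.2) inside Zfhx3, rested on 4 unscaled counts in the EBF1wt library. At Inpp4b, an inositol phosphatase gene, a locus of 2 regions had a ratio of 2.34 (1.71 to 3.27), and at Celf2 a single region had 0.0615 (0.0305 to 0.114).

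The median ratio over all regions lay below 1. On the spike-in scale, the threshold of 100 passed by EBF1wt alone does not account for all of it. The strongest quintile, far above this threshold, still had -0.11 (-0.12 to -0.09). The threshold may account for part of it, since the weakest quintile had -0.34, and together with an error of the scale factor it is not excluded. The scale factor stays open: the median unscaled count ratio was 2.25 and the ratio of the factors 2.5, so an error of the factor could by itself give the whole difference, and its spread could not be set without the human counts. A lower occupancy by EBF1E271A, the difference the design names, and an error of the factor cannot be told apart with 1 library per group.

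The low ratios on chromosome 5 between 130 and 140 Mb were not a chance run of neighbours, since 0 of 10000 shuffles held an interval as low, the smallest p these shuffles can give being 0.0001. Weak loci do not account for them either, since the stronger loci of the interval had a median of -0.43 (-0.99 to -0.27) against -0.11 elsewhere. A copy-number difference of the whole region between the cultures, in all or part of the cells, would shift all loci alike. The interquartile range was 0.809, above 0.703, the upper limit for random sets of matched loci. These sets were matched on mean value and not on which library exceeded 100. In the interval 52% of the loci exceeded it in EBF1wt alone, against 22.7% elsewhere, so the wider spread does not exclude a uniform difference. More copies in both cultures, with unenriched reads adding to each locus, stay open. The lowest ratio of the 50 loci, 0.198 near Eln (0.143 to 0.273), lay below the 0.390 of the chromosome 2 region. That interval covers counting error only, and the ratios of all regions spread more widely than counting error gives. No input value shows the chromosome 2 region to be unenriched, and 12 loci elsewhere also had intervals below its own. These copy-number explanations cannot be told apart from a true loss of EBF1E271A binding there, and a copy gain of part of the region was not tested.

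Low ratios at 6 of the 8 loci with the highest EBF1wt values may come from unenriched reads. The unscaled count ratio was 0.975 (0.961 to 0.988) at the chromosome 2 region and between 1.01 and 1.42 at the other low loci, 2 of them within 2.5 kb of a ribosomal RNA pseudogene, against 2.25 at the median region. Reads from repeats that the antibody did not enrich would follow sequencing depth and not EBF1 occupancy. This and a lower occupancy by EBF1E271A cannot be told apart here, because no input value per region was used to show what unenriched reads give at these loci.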
